A study of Mus musculus with 9 samples.

How the data were processed

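The values used were the deposited gene-level TPM, an abundance corrected for transcript length, with 1 column for each of the 9 samples, which the authors had scaled so that each column had the same sum. The name of the deposited table names salmon, and the submitters' processing notes name DESeq2 and the genome build GRCm38, without versions or roles. Filters applied before deposition were not given in the sources used here. TPM are not counts, so the sequencing depth of the libraries was unknown, and no count-based test was applied. All columns of the table were used, and 22232 genes were at 0 TPM in all 9 samples.

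Genes with at least 1 TPM in at least 3 of the 9 samples were tested, which left 13248 genes. Differences between groups were fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the variance and 1 estimate of the spread shared by the 3 groups, with 6 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Log2 differences come with the standard error of this fit, and TPM come as group means with the SD. No batch is labelled. Positions were taken from GENCODE M21 on GRCm38, which gave length and GC content for 99.6% of the tested genes.

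Before the data were examined, the comparisons, the tests, most of the other settings, the rule for naming genes and 46 gene lists of cell types, tissues and processes were fixed. Of these lists, 45 had at least 5 tested members. The adipose tissue list had 4 and was not tested. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated for each list, with camera on ranks, and with fry, which asks whether the genes of a list move on balance one way. An index is the mean log2(TPM + 1) of the tested members of a list, and its SE comes from the spread between libraries within groups.

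The rule for named genes took, for each comparison, the called genes with a mean of at least 1 TPM over the samples and a symbol that is not that of a predicted gene, a RIKEN clone, a pseudogene or a variable segment of an immunoglobulin or T cell receptor, up to 10 in each direction. Where fewer than 10 genes were called, the 10 with the smallest p under the same conditions were added as values. From each called list it took the 4 members with the smallest p. Pdcd1, Cd274, Ifng, Cxcl9, Gzmb, S100a8, Col1a1 and Sftpc were added whatever their values.

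Unchanged groups were simulated in 100 draws that kept the residual correlation between genes, to count the genes and lists that limma and camera call with no group effect and the overlap that shared controls give. In a self-test of the nanocapsule against anti-PD1 comparison, known 2-fold and 4-fold changes of TPM + 1 were added to 100 genes for each size. At low TPM such a change is larger in TPM itself. With independent noise, limma recovered 69% of 2-fold and 92% of 4-fold changes, with 7 false calls among the unchanged genes of the 13248. With correlated noise it recovered 76% and 98%, with 2 false calls. Each kind of noise was drawn 1 time, and single draws of unchanged groups called up to 2585 genes in this comparison. Each result was recomputed with 1 choice changed at a time, over pseudocounts, filters, scalings, variance models, set tests and the omission of each library. Of these alternatives, 4 were chosen after the data were seen: TPM renormalized without S100a8 and S100a9, the neutrophil granule index as a covariate, a correction of each library for transcript length and GC content, and the omission of the 3 libraries highest in Rag1 and Dntt in their groups.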

Results

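Gene expression was measured by RNA sequencing in the lungs of female BALB/c mice, aged 4 to 6 weeks, that carried tumours of 4T1 cells, a mouse mammary carcinoma line, in the right flank. The mice received phosphate-buffered saline (PBS), an antibody against PD1, or nanocapsules of the antibody on days 7 and 14, and the lungs were collected on day 21. PD1, encoded by Pdcd1, is an inhibitory receptor of activated T cells, and antibodies that block it are given in cancer immunotherapy. The labels state a dose of 150 µg per mouse, in wording that leaves open whether it also holds for the free antibody. Each group had 3 lungs, and 9 libraries were compared. The labels number the lungs within each group without naming the animals, so p-values measure the spread between these samples. The deposited values are TPM, a transcript abundance scaled to the same sum in every library, which keep no sequencing depth, and the depth was therefore unknown. Between 12194 and 13407 genes reached 1 TPM in a library. Spearman correlations between libraries were 0.973 to 0.982 within groups and 0.950 to 0.981 between groups, and no columns were identical.

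The lungs were rich in neutrophil transcripts. S100a8 and S100a9, which encode the main cytosolic proteins of neutrophils, together took 13.8% ± 2.53 of the TPM in the PBS lungs, 11.2% ± 0.842 in the anti-PD1 lungs and 16.2% ± 1.13 in the nanocapsule lungs (SD, n = 3). Transcripts of the mitochondrial genome took 3.55% ± 1.05, 5.41% ± 0.379 and 2.63% ± 0.584 in the same order (SD, n = 3). Within the PBS group, PBS control 2 had the highest S100a8 and S100a9 share, at 16.7%, and the lowest mitochondrial share, at 2.37%, both within 1 percentage point of the nanocapsule means. The median log2 difference over all tested genes was 0.04 for anti-PD1 against PBS, -0.11 for the nanocapsule against PBS and -0.17 for the nanocapsule against anti-PD1. Median-of-ratios scaling brought the last value to -0.03, so differences in that comparison are to be read against this shift. An exact permutation test of 3 lungs against 3 could not give a two-sided p below 0.1.

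The first comparison asked how lungs treated with the free antibody differed from PBS lungs, in a study of possible immune-related adverse effects. A single gene, Hspa1b, which encodes an inducible heat shock protein of the HSP70 family, was lower in the anti-PD1 lungs. It lies on chromosome 17 from 34956436 to 34959238 of GRCm38 and is protein coding. Its level was 40.7 ± 12.2 TPM in the PBS lungs and 9.64 ± 0.423 TPM in the anti-PD1 lungs (SD, n = 3), a log2 difference of -1.93 (SE 0.21, limma adjusted p = 0.0445), and all 3 anti-PD1 lungs lay below all 3 PBS lungs. Its neighbour Hspa1a, a near-identical copy with which reads can be exchanged, had a log2 difference of -1.57 (SE 0.23, limma adjusted p = 0.156), so the level of each copy is uncertain. Of 13248 genes tested, 2192 had an unadjusted p under 0.05, 1124 higher and 1068 lower. The Hspa1b call was lost in 7 of the 9 fits that left out 1 library, with adjusted p up to 0.191. It was kept without PBS control 1 or nanocapsule 1, each of which gave 3 called genes.

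Neutrophil genes were lower in the anti-PD1 lungs than in the PBS lungs, by value. Of 20 genes of neutrophil granules and neutrophil precursors, 19 had lower means, with an index difference of -0.53 (SE 0.11) in mean log2(TPM + 1). Elane, the gene of neutrophil elastase, was at 12.2 ± 1.87 TPM in the PBS lungs and 5.32 ± 0.526 TPM in the anti-PD1 lungs, Mpo, the gene of myeloperoxidase, at 19.2 ± 1.55 and 8.90 ± 0.723 TPM, and Cebpe, a transcription factor of granulocyte maturation, at 32.3 ± 5.78 and 18.9 ± 0.916 TPM (SD, n = 3). Adjusted over the list alone, 13 granule genes passed, all lower, and limma called none of the list over all genes. Of 19 mature neutrophil genes, 18 had lower means. Among them, Mmp9 was at 983 ± 272 and 566 ± 21.6 TPM and Ly6g at 518 ± 104 and 347 ± 31.1 TPM (SD, n = 3). Camera with a preset correlation called both lists (adjusted p = 9.49e-13 and 1.54e-09), and with an estimated correlation neither was called (adjusted p = 0.417 and 0.566).

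Genes of eosinophils, basophils and mast cells were also lower by value, 12 of 15, with an index difference of -0.67 (SE 0.11). Prg2, the eosinophil major basic protein, was at 34.9 ± 10.6 TPM in the PBS lungs and 6.66 ± 2.86 TPM in the anti-PD1 lungs (SD, n = 3), a log2 difference of -2.27 (SE 0.29, limma adjusted p = 0.0894). Ear6, an eosinophil-associated ribonuclease, was at 36.4 ± 10.3 and 11.5 ± 3.66 TPM (SD, n = 3). The preset camera test called the list (adjusted p = 1.01e-05), and the adjusted p was 0.417 with an estimated correlation. Among 12 genes of type 2 responses, 8 were lower, with Ccl24, an eosinophil chemoattractant, at 14.2 ± 3.94 and 6.08 ± 0.813 TPM (SD, n = 3; list adjusted p = 0.0323 preset, and adjusted p = 0.663 with an estimated correlation).

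Endothelial genes stood higher in the anti-PD1 lungs, 19 of 19, with an index difference of 1.07 (SE 0.39). Relative to the PBS mean, the index lay at -0.65 in PBS control 2, at 0.18 and 0.46 in PBS control 1 and 3, and at 0.75 to 1.52 in the anti-PD1 lungs. Tmem100 was at 5.06 ± 2.77 TPM in the PBS lungs and 16.7 ± 5.95 TPM in the anti-PD1 lungs, and Kdr, the main receptor of vascular endothelial growth factor, at 3.12 ± 1.61 and 7.92 ± 2.20 TPM (SD, n = 3). Of these genes, 13 passed when adjusted over the list alone and none over all genes. The list was called by the preset camera test (adjusted p = 1.54e-09), and the adjusted p was 0.663 with an estimated correlation. The 13 genes of the mitochondrial genome, all higher by value, had an index difference of 0.76 (SE 0.31; adjusted p = 3.18e-07 preset, and adjusted p = 0.665 with an estimated correlation). It was 0.43 without PBS control 2. Genes of blood stood higher with them: 8 of 8 erythroid genes, with an index difference of 1.19 (SE 0.63; adjusted p = 0.000739 preset, and adjusted p = 0.672 with an estimated correlation), and 10 of 11 platelet and megakaryocyte genes, with one of 0.48 (SE 0.22; adjusted p = 0.00177 preset, and adjusted p = 0.672 with an estimated correlation). The platelet value was 0.29 without PBS control 2 and 0.32 without anti-PD1 2. Haemoglobin transcripts took 0.714% ± 0.529 of the TPM in the PBS lungs and 1.74% ± 0.734 in the anti-PD1 lungs (SD, n = 3). Alveolar macrophage genes were higher in 20 of 20 members, with Ear2 at 704 ± 148 and 1149 ± 80.1 TPM (SD, n = 3; list adjusted p = 2.86e-06 preset, and adjusted p = 0.672 with an estimated correlation). Relative to the PBS mean, their index lay at -0.47 in PBS control 2, at 0.39 and 0.08 in PBS control 1 and 3, and at 0.42 to 0.63 in the anti-PD1 lungs. Sftpc, the surfactant protein C gene of alveolar type 2 cells, was at 723 ± 346 and 2017 ± 1130 TPM (SD, n = 3; limma adjusted p = 0.279). In the cytotoxic lymphocyte list, all 20 genes had higher means, with Klrd1 at 9.78 ± 1.64 and 15.7 ± 2.60 TPM (SD, n = 3; list adjusted p = 0.00128 preset, and adjusted p = 0.672 with an estimated correlation). The index difference of this list was 0.39 (SE 0.21), and 0.23 without anti-PD1 3, the library with the highest Rag1, at 28.3 TPM, and Cd8a, at 54.8 TPM. Cardiac muscle genes were higher in 9 of 10 members (adjusted p = 0.00195 preset, and adjusted p = 0.672 with an estimated correlation), at low levels such as 0.505 ± 0.319 and 2.26 ± 0.988 TPM for Tnnt2 (SD, n = 3).

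In all, the preset camera test called 19 of 45 lists for anti-PD1 against PBS, 12 up and 7 down, and no list was called with an estimated correlation. Simulated unchanged groups with the residual correlation of these lungs gave a median of 18 called lists over 100 draws, and 41 draws gave at least 19, so the number of called lists did not exceed what unchanged groups gave. In these draws, 2 of 100 called at least 1 gene and 12 had at least 2192 genes at an unadjusted p under 0.05. Type I interferon response genes had lower means in 23 of 25 members, with an index difference of -0.25 (SE 0.19; list adjusted p = 2.33e-05 preset, and adjusted p = 0.686 with an estimated correlation). It was -0.09 without PBS control 3, -0.42 without PBS control 1 and -0.39 without anti-PD1 2. The next 3 lists were not called: the index difference was -0.04 (SE 0.12) for interferon gamma response genes, -0.08 (SE 0.15) for inflammatory cytokines and chemokines and 0.30 (SE 0.18) for genes of fibrosis and extracellular matrix. Without single libraries, the first value lay between -0.10 (without PBS control 2) and 0.06 (without PBS control 3), and the second between -0.17 (without PBS control 3) and 0.01 (without PBS control 1). The third was 0.13 without PBS control 2. The medians of the first 2 lists changed sign without the mitochondrial, haemoglobin and immunoglobulin genes. Pdcd1 itself was at 1.88 ± 1.12 and 3.36 ± 1.93 TPM, Ifng at 3.29 ± 1.48 and 3.54 ± 0.154 TPM and Gzmb at 10.4 ± 2.37 and 13.8 ± 2.70 TPM (SD, n = 3; limma adjusted p = 0.462, 0.835 and 0.515).

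The second comparison asked the same question of the nanocapsules. Hspa1b was lower in the nanocapsule lungs than in the PBS lungs, and other heat shock genes stood lower by value. Hspa1b was at 6.85 ± 1.62 TPM (SD, n = 3), a log2 difference of -2.39 from the PBS lungs (SE 0.21, limma adjusted p = 0.00623), and all 3 nanocapsule lungs lay below all 3 PBS lungs. By value, Hspa1a had a log2 difference of -1.66 (SE 0.23, limma adjusted p = 0.0803), Dnaja1, a co-chaperone of HSP70, one of -0.90 (SE 0.11, limma adjusted p = 0.0502), and Hsph1 and Hsp90aa1, further chaperone genes, had differences of -1.45 and -0.76 (SE 0.25 and 0.13). The list of 13 immediate early and 7 heat shock genes, with 19 of 20 members lower, was called by the preset camera test (adjusted p = 1.71e-07) and by fry (adjusted p = 0.0129), and the adjusted p was 0.307 with an estimated correlation. Hspa1b was the 1 gene called, with 1343 genes at an unadjusted p under 0.05, 161 higher and 1182 lower, and the call was lost without PBS control 3, nanocapsule 1 or nanocapsule 3, with adjusted p up to 0.125. Limma called 3 genes without PBS control 1 and 4 without PBS control 2.

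B cell and T cell genes stood lower by value in the nanocapsule lungs. All 16 B cell genes had lower means, with an index difference of -0.94 (SE 0.33), and 13 passed when adjusted over the list alone and none over all genes. Ms4a1, the CD20 gene, was at 46.6 ± 11.5 TPM in the PBS lungs and 19.2 ± 2.58 TPM in the nanocapsule lungs, and Cxcr5, a chemokine receptor of B cells, at 20.4 ± 1.90 and 10.9 ± 1.25 TPM (SD, n = 3). The preset camera test called the list (adjusted p = 4.78e-12), and the adjusted p was 0.492 with an estimated correlation. Plasma cell and immunoglobulin genes were lower in 16 of 17 members, with Ighm at 455 ± 99.1 and 230 ± 20.2 TPM (SD, n = 3; list adjusted p = 1.10e-05 preset, and adjusted p = 0.593 with an estimated correlation). MHC class II genes were lower in 11 of 11 members, with H2-Ob at 27.1 ± 11.6 and 11.2 ± 1.12 TPM (SD, n = 3; list adjusted p = 0.000159 preset, and adjusted p = 0.626 with an estimated correlation). All 20 T cell genes had lower means, with an index difference of -0.60 (SE 0.42; list adjusted p = 0.000282 preset, and adjusted p = 0.731 with an estimated correlation), and the list was not called without PBS control 3 or nanocapsule 3. Without PBS control 3, which had Rag1 at 8.62 TPM and Dntt at 14.1 TPM, the index difference was -0.30. The cytotoxic lymphocyte list, with 14 of 20 members lower and 6 higher, was not called, with an index difference of -0.21 (SE 0.21; camera adjusted p = 0.488). That value was -0.39 without nanocapsule 1, -0.09 without nanocapsule 3 and -0.11 without PBS control 3. Checkpoint and co-stimulation genes were lower in 13 of 15 members, with Ctla4 at 5.03 ± 0.927 and 2.02 ± 0.533 TPM (SD, n = 3; list adjusted p = 2.89e-05 preset, and adjusted p = 0.593 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, was at 4.04 ± 0.770 and 1.86 ± 0.346 TPM and Pdcd1 at 1.88 ± 1.12 and 0.568 ± 0.153 TPM (SD, n = 3; limma adjusted p = 0.338 and 0.507).

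Eosinophil, basophil and mast cell genes were lower here too, 13 of 15, with an index difference of -0.73 (SE 0.11). Prg2 was at 11 ± 1.36 TPM and Ear6 at 14.8 ± 2.19 TPM in the nanocapsule lungs (SD, n = 3; list adjusted p = 4.57e-05 preset, and adjusted p = 0.426 with an estimated correlation). Genes of the unfolded protein response were lower in 16 of 18 members, with Hspa5, the chaperone BiP, at 295 ± 23.2 and 202 ± 24.3 TPM (SD, n = 3; list adjusted p = 0.000126 preset, and adjusted p = 0.593 with an estimated correlation). Neutrophil granule genes stood slightly higher, 18 of 20, with an index difference of 0.24 (SE 0.11; adjusted p = 7.09e-11 preset, and adjusted p = 0.426 with an estimated correlation). It was 0.36 without PBS control 2. The endothelial index differed by -0.06 (SE 0.39), less than its error, and lay between -0.38 (without PBS control 2) and 0.18 (without PBS control 3) with single libraries left out. Cardiac muscle genes were higher in 9 of 10 members, with an index difference of 0.60 (SE 0.32; adjusted p = 3.46e-07 preset, and adjusted p = 0.426 with an estimated correlation). It was 0.39 without nanocapsule 1 and 0.95 without nanocapsule 2. Erythroid genes were higher in 8 of 8 members, with an index difference of 0.49 (SE 0.63; adjusted p = 0.00105 preset, and adjusted p = 0.626 with an estimated correlation). It was -0.04 without nanocapsule 1, 1.0 without nanocapsule 3, 0.87 without PBS control 1 and 0.20 without PBS control 2. Of 45 lists, 18 were called by the preset camera test, 6 up and 12 down, and none with an estimated correlation, and the simulated unchanged groups gave a median of 18. For 1 called list, of the lysosome, the median (-0.01) and the test (up) had different signs. Of the simulated draws, 3 of 100 called at least 1 gene and 11 had at least 1343 genes at an unadjusted p under 0.05. Interferon gamma response genes had lower means in 21 of 23 members, with an index difference of -0.33 (SE 0.12; list adjusted p = 0.00221 preset, and adjusted p = 0.626 with an estimated correlation). This list was not called without nanocapsule 3. The lists of inflammatory cytokines and chemokines and of fibrosis and extracellular matrix were not called, with index differences of -0.20 (SE 0.15) and -0.10 (SE 0.18). The first was -0.09 without nanocapsule 2, -0.30 without nanocapsule 3 and -0.11 without PBS control 1. The second was -0.27 without PBS control 2, -0.04 without PBS control 3 and above 0 without PBS control 1, and the median of that list changed sign with median-of-ratios or quantile scaling.

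**Figure D1:**
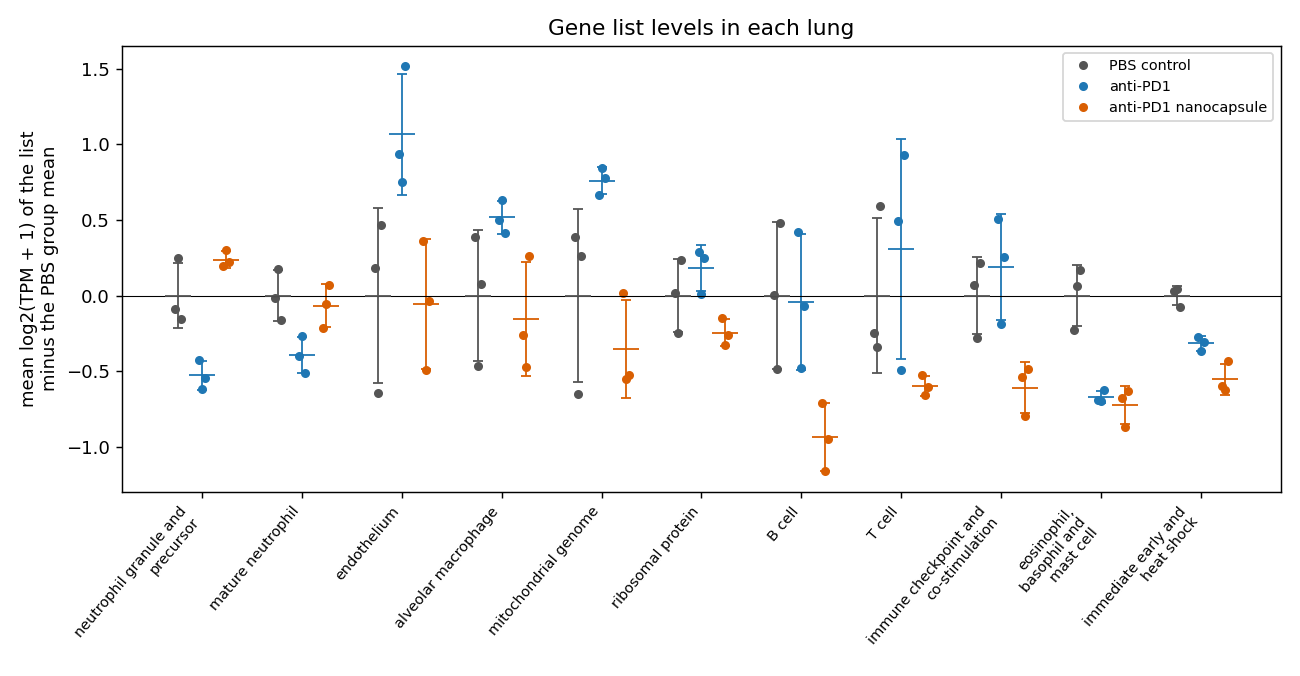
Mean log2(TPM + 1) of 11 gene lists in each lung, as the difference from the mean of the 3 PBS lungs on a linear axis. Points are single lungs, horizontal marks group means and bars 1 SD (n = 3). The neutrophil granule index lay at -0.53 ± 0.10 in the anti-PD1 lungs and 0.24 ± 0.05 in the nanocapsule lungs, and the eosinophil, basophil and mast cell index lay at -0.67 ± 0.04 and -0.73 ± 0.13.

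The third comparison set the nanocapsule lungs against the free antibody lungs. Of the 14 genes called by limma, 9 were higher in the nanocapsule lungs, and 3 of these, Elane, Cebpe and Padi4, are among the 20 members of the neutrophil granule list. The called genes included Elane (log2 difference 1.23, SE 0.16), Cebpe (1.01, SE 0.12), Padi4, a peptidylarginine deiminase of neutrophils (0.88, SE 0.13), Cd177, a neutrophil surface glycoprotein (0.85, SE 0.13), and Ceacam10 (0.82, SE 0.12), with adjusted p = 0.0393, 0.0393, 0.0448, 0.0448 and 0.0448. In each of these 5 genes all 3 nanocapsule lungs lay above all 3 anti-PD1 lungs. Elane, on chromosome 10 from 79886247 to 79888215 of GRCm38, was at 13.9 ± 2.43 TPM in the nanocapsule lungs and 5.32 ± 0.526 TPM in the anti-PD1 lungs, and Cd177, on chromosome 7 from 24743983 to 24760311, at 595 ± 10.7 and 329 ± 26.3 TPM (SD, n = 3). The other genes called higher within the naming rule were Ckap4 (0.86, SE 0.12), Cep19 (0.80, SE 0.09) and Ethe1 (0.71, SE 0.10).

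The called genes that were lower in the nanocapsule lungs were not of one list. Hnrnph1, a splicing factor, was at 105 ± 2.19 TPM in the nanocapsule lungs and 155 ± 10.5 TPM in the anti-PD1 lungs, Snhg20, a small nucleolar RNA host gene, at 12.3 ± 1.10 and 22.9 ± 2.28 TPM, and AA465934, a transcript on chromosome 11, at 0.561 ± 0.179 and 3.53 ± 0.180 TPM (SD, n = 3), with log2 differences of -0.56 (SE 0.08), -0.84 (SE 0.11) and -1.54 (SE 0.19) and limma adjusted p = 0.0442, 0.0393 and 0.0393. Gm28438 shares sequence with the mitochondrial genome, so its reads are uncertain, and Trav5-1, a T cell receptor segment, was listed at 0 TPM in all 3 nanocapsule lungs. Both were named after their values were seen, as was 4930438A08Rik, a called gene that was higher (1.01, SE 0.13).

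The neutrophil granule list had 19 of 20 members higher in the nanocapsule lungs, with an index difference of 0.77 (SE 0.11). It was called by the preset camera test (adjusted p = 1.01e-23) and by fry (adjusted p = 0.0205), and the adjusted p was 0.345 with an estimated correlation. Adjusted over the list alone, 19 of its genes passed, and 3 did over all genes. Mature neutrophil genes were higher in 17 of 19 members, with Retnlg at 8761 ± 1534 and 4769 ± 137 TPM and Ly6g at 659 ± 70.9 and 347 ± 31.1 TPM (SD, n = 3; list adjusted p = 8.39e-09 preset, and adjusted p = 0.680 with an estimated correlation). S100a8 was at 72701 ± 2419 and 47655 ± 1649 TPM (SD, n = 3; limma adjusted p = 0.124). Genes of hypoxia and glycolysis were higher in 14 of 20 members, with Pgk1 at 323 ± 10.5 and 231 ± 13.4 TPM (SD, n = 3; list adjusted p = 2.98e-07 preset, and adjusted p = 0.660 with an estimated correlation). Monocyte and interstitial macrophage genes, 11 of 20 higher, had an index difference of 0.03 (SE 0.06; list called up, adjusted p = 0.0228 preset, and adjusted p = 0.680 with an estimated correlation). It was 0.07 without nanocapsule 2, 0.08 without anti-PD1 1, 0.02 without anti-PD1 2, -0.02 without nanocapsule 3 and -0.01 without anti-PD1 3. The median of the list changed sign without the mitochondrial, haemoglobin and immunoglobulin genes.

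Endothelial, lymphoid and mitochondrial genes stood lower by value in the nanocapsule lungs. All 19 endothelial genes had lower means, with an index difference of -1.12 (SE 0.39), and Pecam1, the CD31 gene, was at 16.9 ± 4.6 TPM in the nanocapsule lungs and 35.2 ± 8.39 TPM in the anti-PD1 lungs (SD, n = 3; list adjusted p = 5.36e-06 preset, and adjusted p = 0.680 with an estimated correlation). All 13 mitochondrial genome genes had lower means, with an index difference of -1.12 (SE 0.31; adjusted p = 2.98e-07 preset, and adjusted p = 0.680 with an estimated correlation). All 20 T cell genes, 16 B cell genes and 7 regulatory T cell genes had lower means, with index differences of -0.91 (SE 0.42), -0.90 (SE 0.33) and -0.87 (SE 0.22). Their preset camera tests gave adjusted p = 0.000124, 1.77e-05 and 0.00141, and with an estimated correlation the adjusted p was 0.708, 0.680 and 0.680. Cd2, a T cell adhesion receptor, was at 90.5 ± 15.0 and 151 ± 4.75 TPM (SD, n = 3; limma adjusted p = 0.0527). T cell values varied widely between the anti-PD1 lungs, with Rag1 at 28.3 TPM in anti-PD1 3 and 0.932 TPM in anti-PD1 2. The T cell index difference was -0.60 without anti-PD1 3. Pdcd1 was at 0.568 ± 0.153 and 3.36 ± 1.93 TPM and Cd274, the gene of its ligand PD-L1, at 22.3 ± 7.26 and 41.1 ± 5.51 TPM (SD, n = 3; limma adjusted p = 0.0862 and 0.0736).

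The 14 called genes lay close to the threshold: 1234 genes had an adjusted p under 0.1, 394 higher and 840 lower. Leaving out single libraries gave between 0 and 962 called genes: 0 without anti-PD1 1, anti-PD1 2 or nanocapsule 2, 1 without anti-PD1 3 or nanocapsule 3, 5 without nanocapsule 1, 188 without PBS control 3 and 962 without PBS control 2. The split of 9 higher and 5 lower calls became 60 and 15 with quantile normalization, 19 and 2 with median-of-ratios scaling, and 63 and 108 without the mitochondrial, haemoglobin and immunoglobulin genes. Of 45 lists, 20 were called by the preset camera test, 6 up and 14 down, against a median of 17 in simulated unchanged groups, and none with an estimated correlation. At least 14 called genes came in 1 of 100 simulated draws, and at least 3670 genes at an unadjusted p under 0.05 in 1. For 2 called lists, type I interferon response and NRF2 targets, the median and the test had different signs, and the medians changed sign with median-of-ratios or quantile scaling.

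**Figure D2:**
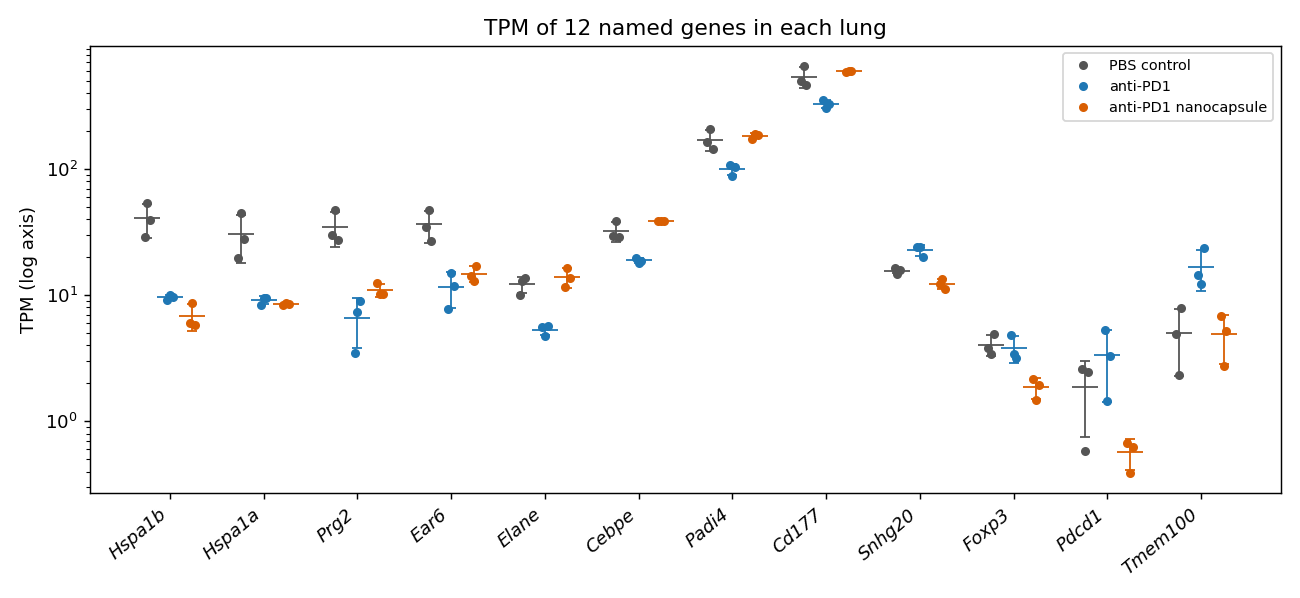
TPM of 12 named genes in each lung on a log axis. Points are single lungs, horizontal marks group means and bars 1 SD (n = 3). Hspa1b lay between 29.1 and 53.5 TPM in the PBS lungs and between 5.80 and 10.1 TPM in the treated lungs, and Elane lay at 4.72 to 5.70 TPM in the anti-PD1 lungs and at 10.1 to 16.5 TPM in the other lungs.

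The 2 comparisons with PBS shared their 3 control lungs. Hspa1b was the 1 gene called lower in both. Simulated unchanged groups against these controls gave a mean of 20.4 shared calls, all from a small share of the draws. The central range of the draws was 0 to 0, so the observed 1 lay above that range though below the mean. Independent lists of this size would share 7.55e-05 genes. Of genes with an unadjusted p under 0.05 in the same direction in both, there were 176, against a simulated mean of 187.5 and an independent overlap of 109. Across genes, which are not independent replicates, the log2 differences of both comparisons had a Pearson correlation of 0.24, against a simulated mean of 0.45 (central range of the draws -0.28 to 0.95). Their covariance was 0.0213 against a simulated 0.0285, a difference of -0.00725. The 3 controls could not be split into parts of at least 2, and no value free of the shared controls was obtained.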

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

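The tests of technical explanations and the counts of other splits were chosen or worded after the results were seen. The results given here are genes whose effect against PBS differed between the anti-PD1 and the nanocapsule lungs, by limma's test with 3 lungs per group. The PBS mean cancels in this difference. These are therefore the genes and tests of the third comparison again, and they add no separate support.

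Of the 14 genes, 9 had a positive difference and 5 a negative one, and Elane, Cebpe and Padi4 are members of the neutrophil granule list. The difference between the effects, nanocapsule minus anti-PD1, was 1.23 in log2 for Elane, with effects against PBS of 0.17 and -1.05. For Cebpe it was 1.01 (0.27 and -0.74), for Padi4 0.88 (0.11 and -0.76), for Cd177 0.85 (0.16 and -0.70) and for Ceacam10 0.82 (0.20 and -0.63). Ckap4 differed by 0.86 (0.36 and -0.51), Cep19 by 0.80 (0.20 and -0.60), Ethe1 by 0.71 (0.41 and -0.30) and 4930438A08Rik by 1.01 (0.45 and -0.56). In the other direction, Hnrnph1 differed by -0.56 (-0.33 and 0.23), Snhg20 by -0.84 (-0.32 and 0.52) and AA465934 by -1.54 (-0.98 and 0.57). Gm28438 differed by -1.44 (-0.53 and 0.91) and shares sequence with the mitochondrial genome. Trav5-1 differed by -1.52 in the fit (-1.67 and -0.14), a value that depends on the pseudocount because the gene was listed at 0 TPM in the nanocapsule lungs.

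The pattern weighed here is that neutrophil granule genes stood higher and endothelial genes lower in the nanocapsule than in the anti-PD1 lungs. S100a8 and S100a9 took 11.2% of the TPM in the anti-PD1 and 16.2% in the nanocapsule lungs, shares whose removal can shift an index only slightly. After both were removed and TPM renormalized, the endothelial index differed by -1.07 (SE 0.38), against -1.12 before. The size of these shares, which fixed this outcome, argues against them as the whole cause. After a correction for transcript length and GC content, the granule index minus the endothelial index still differed by 1.94 (SE 0.49), which argues against such a bias as the whole cause. A larger neutrophil share that dilutes every other cell type alike predicts equal falls. The endothelial index minus the monocyte index differed by -1.16 (SE 0.40), but monocyte genes are partly expressed by neutrophils. The eosinophil, basophil and mast cell index differed by -0.06 (SE 0.11). Other indices fell: T cell by -0.91 (SE 0.42), B cell by -0.90 (SE 0.33), and fibroblast, pericyte and smooth muscle by -0.67 (SE 0.21). The alveolar macrophage index differed by -0.67 (SE 0.28). The monocyte list alone cannot decide on an equal dilution. The eosinophil, basophil and mast cell index, which did not fall beyond its error, argues against an equal dilution of every other cell type. A dilution shared by the lists that fell stays open. A change in the neutrophils or in the endothelium of the treated lungs, or in the piece of lung taken, may remain and was not tested. Variation between lungs apart from treatment was not tested either. PBS control 2 had a granule index of 8.65 and an endothelial index of 2.39, beside 8.70 and 2.54 in nanocapsule 2. PBS control 1 had 8.31 and 3.21, and PBS control 3 had 8.25 and 3.50.

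Splits of 6 lungs into groups of 3 number 10, too few for a share under 0.05. For anti-PD1 against PBS, 3 of 10 splits gave as many genes as the real one, which gave 1, and the highest other gave 17. For the nanocapsule against PBS, 3 of 10 gave as many as the real 1, and the highest other gave 34. Simulated unchanged groups gave a median of 0 genes in these comparisons and up to 4380 and 2056 in single draws. The split with 17 genes followed Rag1. It set PBS control 1, PBS control 2 and anti-PD1 2, at 0.338, 0.460 and 0.932 TPM, against PBS control 3, anti-PD1 1 and anti-PD1 3, at 8.62, 3.46 and 28.3 TPM. Whether the split with 34 genes reflects a structure of the samples stays open. For the nanocapsule against anti-PD1, 1 of 10 splits, the real one, gave 14 genes, and the highest other gave 0. For gene lists, 5, 4 and 4 of 10 splits gave as many as the real 19, 18 and 20, and the highest others gave 24, 24 and 23. For genes called in both PBS comparisons, 6 of 100 splits gave as many as the real 1, the highest other gave 21, and chance cannot be excluded.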

How the results depend on the processing

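The renormalization without S100a8 and S100a9, the granule index as covariate, the length and GC correction and the omission of 3 libraries were chosen after the data were seen, and the cause of a change was not tested unless stated. For anti-PD1 against PBS, limma called 1 gene in the fit reported, where 2192 had an unadjusted p under 0.05. It called 0 genes with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization or no variance trend. The count was also 0 without S100a8 and S100a9, with the covariate, or with the length and GC correction. A pseudocount of 5 gave 2 genes and sample weights gave 279. Leaving out single libraries gave 0 to 3. For the nanocapsule against PBS, 2 genes were called with a pseudocount of 0.1, no variance trend or the length and GC correction, 4 with median-of-ratios scaling, robust variance or no S100a8 and S100a9, 0 with quantile normalization, no filter or 3 libraries left out, 3 without mitochondrial, haemoglobin and immunoglobulin genes, 5 with the replicate block and 9 with sample weights. Leaving out single libraries gave 0 to 4. For the nanocapsule against anti-PD1, 75 genes were called with quantile normalization, 2 with no variance trend, 3421 with sample weights, 72 without S100a8 and S100a9, 0 with the covariate, 37 with the length and GC correction, 3 with no filter, 171 without mitochondrial, haemoglobin and immunoglobulin genes, 79 with robust variance, 1095 with the replicate block, 1 with 3 libraries left out, 182 with TPM of at least 5 (fewer genes tested) and 476 with 2 groups in the fit. Leaving out single libraries gave 0 to 962. The replicate numbers were not taken as pairs, since the labels do not say that they mark a shared animal, day or cage. Same-number correlations were -0.18 to 0.28, and 6 of 9 libraries had their best match in another group at their own number. A factor shared by lungs of the same number is therefore not excluded. Genes called in both PBS comparisons numbered 0 with a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, no variance trend, no S100a8 and S100a9, the covariate, the length and GC correction or 3 libraries left out, 3 with sample weights, and 0 to 2 without single libraries. Camera with an estimated correlation called 0, 0 and 0 lists and fry 0, 1 and 1. The mixed form of fry, which asks whether genes of a list move in either direction, called 5, 2 and 21. It was not run on the simulated unchanged groups. With the covariate, camera called 12 lists for the nanocapsule against anti-PD1, 10 up and 2 down, of which 1 was among the 20 lists called without it. For anti-PD1 against PBS the covariate gave 13 lists, 2 up and 11 down, of which 3 were among the 19. The correlation of the log2 differences was -0.26 with the covariate, 0.42 with 3 libraries left out, and 0.09 to 0.40 (0.0853 to 0.397) without single libraries. With the covariate, Padi4 and Cd177 reversed, to -0.03 (-0.0281) and -0.03 (-0.0251). The covariate averages a list that holds Elane, Cebpe and Padi4. It lay at 7.79 to 7.98 in the anti-PD1 lungs and at 8.60 to 8.70 in the nanocapsule lungs, so it nearly stood in for the group. Calls lost or reversed with it in that comparison were largely given in advance and do not show whether the groups differ. For the 16 called differences of named genes, 224 of 398 values under the alternatives kept the call, 172 lost it and 2 reversed, and 322 values of uncalled named genes passed the threshold under an alternative. The unknown depth sets no limit that could be computed.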

Other observations

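The tests of explanations in this part were chosen after the results were seen. The gene lists in the first paragraph were fixed before the data were examined.

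Further lists moved by value. In the anti-PD1 lungs, 16 of 20 genes of hypoxia and glycolysis had lower means than in the PBS lungs, with an index difference of -0.24 (SE 0.06; camera adjusted p = 1.90e-06, and adjusted p = 0.433 with an estimated correlation). Fibroblast, pericyte and smooth muscle genes stood higher in 12 of 13 members, at 0.56 (SE 0.21; adjusted p = 0.000739, and adjusted p = 0.663 with an estimated correlation), and alveolar type 1 genes in 12 of 13, at 0.62 (SE 0.25; adjusted p = 0.00126, and adjusted p = 0.669 with an estimated correlation). In the nanocapsule against the anti-PD1 lungs, 28 of 28 ribosomal protein genes had lower means, at -0.43 (SE 0.14; adjusted p = 2.98e-07, and adjusted p = 0.680 with an estimated correlation), and 20 of 20 alveolar macrophage genes did, at -0.67 (SE 0.28; adjusted p = 6.97e-05, and adjusted p = 0.708 with an estimated correlation).

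The mean log2 difference of 7 heat shock genes from the PBS lungs was -0.67 (SE 0.10) for anti-PD1 and -1.11 (SE 0.10) for the nanocapsule, and without Hspa1a and Hspa1b that of the other 5 was -0.24 (SE 0.18), within 2 SE of 0, and -0.75 (SE 0.18). Reads shared between Hspa1a and Hspa1b are argued against by their summed TPM, which differed by -1.82 (SE 0.25) and -2.09 (SE 0.25). With the granule index as covariate, the 7 genes were at -0.73 (SE 0.22) and -1.09 (SE 0.14). That index lay at 8.25 to 8.65 in the PBS, 7.79 to 7.98 in the anti-PD1 and 8.60 to 8.70 in the nanocapsule lungs. It did not overlap between the PBS and the anti-PD1 lungs, so it cannot part the neutrophil share from the group there. For the nanocapsule, where it overlapped, the value argues against the share, as granule genes measure it, as the whole cause. The anti-PD1 call of Hspa1b ended with the covariate, as its difference went from -1.93 (SE 0.21) to -1.20 with a wider error. Tissue handling before lysis may have differed between groups and cannot be told apart from treatment, since immediate early genes differed by -0.12 (SE 0.11) in the anti-PD1 lungs, within 2 SE of 0, and by -0.25 (SE 0.11) in the nanocapsule lungs, beyond 2 SE and in the direction that handling predicts. A biological effect of the treatments stays open and untested.

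Rag1 and Dntt, which act in the rearrangement of antigen receptor genes in precursors of lymphocytes, were highest in 1 library of each group, at 28.3 and 46.8 TPM in anti-PD1 3, 8.62 and 14.1 TPM in PBS control 3 and 4.72 and 12.1 TPM in nanocapsule 2, and anti-PD1 1 followed with 3.46 and 4.49 TPM. A candidate explanation is thymus tissue in the lung piece: the mean of 6 thymocyte genes followed Dntt over the 9 libraries with a Pearson r of 0.979 (exact permutation p = 0.000187, adjusted 0.000375 over 2 relations) and a Spearman rho of 0.817 (exact permutation p = 0.0108, adjusted 0.0215). Without anti-PD1 3 and PBS control 3, r was 0.966 (exact permutation p = 0.0135) and rho 0.607 (exact permutation p = 0.167), and 2 of the 6 genes, Satb1 (88.7 TPM in anti-PD1 3) and Ccr9 (24.3 TPM), reached 1 TPM in all libraries. B cell precursors stay open: 4 genes, of which Vpreb3 alone reached 1 TPM in all libraries (6.04 to 24.5 TPM), gave r = 0.542 (exact permutation p = 0.135) and a rho of 0.450 (exact permutation p = 0.230), and r = -0.146 without the same libraries (exact permutation p = 0.766).

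Tmem254a was at 5.02 to 11.8 TPM in the anti-PD1 lungs and at most 0.327 TPM in the PBS lungs, and Tmem254b at most 0.189 TPM and 5.66 to 8.12 TPM. In nanocapsule 1, 2 and 3, Tmem254a was at 4.20, 0.236 and 0 TPM and Tmem254b at 0, 4.32 and 4.68 TPM. The exchange thus parted the PBS from the anti-PD1 lungs but was mixed within the nanocapsule group. The sum of Tmem254a, Tmem254b and Tmem254c was 9.28 to 14.3 TPM in the 9 libraries.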
